A study of Drosophila melanogaster with 4 samples.

How the data were processed

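The series compared central brains of Drosophila melanogaster pupae labelled female, 24 h after puparium formation and raised at 29 °C. A control genotype (OK107-Gal4 with UAS-dicer2) was set against the same genotype with an inverted repeat against DIP2. Each group held 2 samples, which the series' design text calls biological replicates. The sample source text also names the white pupa, an earlier stage than 24 h; the stage given in the characteristics was kept.

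Per the labels, total RNA was amplified, labelled with Cy3 and hybridised to Agilent arrays, 1 sample per array. Per the file headers and the submitters' processing notes, the scans were extracted with Agilent Feature Extraction 10.5.1.1, which the authors used to write a processed intensity per spot that was already background-subtracted and detrended within the array, beside the uncorrected mean intensity and the local background intensity. The authors also deposited a table of log2 values for the same 43602 spots, whose normalization is not given in the sources used here. Set against the scanner files by feature number, the columns had nearly the same distribution (each with a median of 7.89), were not centred per gene and ran in the same direction. Within each group, however, each column followed the scanner file of the other replicate: across 16889 spots, deviations of the column of control replicate 1 correlated at 0.923 with the scanner file of control replicate 2, and those of the column of knockdown replicate 1 at 0.838 with the file of knockdown replicate 2. The replicate numbers below are those of the scanner files. This exchange leaves the group means as they are.

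The log2 processed intensity of each spot was reduced by the 75th percentile of its array over the non-control spots. Outlier-marked spots were left out, and spots of a probe were averaged. A probe was tested if it was well above background on both arrays of at least 1 group. Probes were matched to genes through the CG number, RefSeq accession or symbol in the files and a RefSeq gene table (Release 6 plus ISO1 MT, used for names only). Of 32162 probes, 21050 matched 1 gene, 17 matched several and 11095 matched none. A gene was represented by its brightest tested probe, which left 9646 genes. For genes named by the rule below, other probes are given where their median difference had the opposite sign. Smaller disagreement between probes is given for some genes only. Positions are those of the probes on dm3 (BDGP release 5), as in the files.

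Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The fit had 2 residual degrees of freedom per gene and gained 3.09 from the prior, and the number of arrays limits the precision. Arrays in groups of 2 allow no exact permutation p below 0.333 for a single value. As a description without a test, genes were counted whose 2 knockdown arrays both lay at least 1.5-fold above, or below, both control arrays. A gene whose chosen probe was not well above background on any array of a group has only a bound there: the fold is given as "at least", from the bright group's mean against, on each array of the dim group, the higher of the probe's own signal and the lowest signal among probes well above background on that array.

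A total of 24 gene lists, with at least 5 measured members each, of which 23 are reported (mushroom body neurons, axon guidance and branching, JNK pathway, ecdysone response, glia, neuroblasts and cell cycle, synaptic transmission, neuropeptides, photoreceptors and optic lobe, fat body and haemolymph, haemocytes, muscle, cuticle and epidermis, heat shock and chaperones, immune and stress effectors, small RNA pathway, lipid and acyl-CoA metabolism, DNA repair and topoisomerases, detoxification, cytosolic ribosomal proteins, proteasome, oxidative phosphorylation, dosage compensation and sex), were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists) and, beside it, with an estimated correlation, on ranks, and with fry. The groups, tests, lists and the alternatives named below were fixed before the data were examined, apart from a second background correction that is marked as chosen afterwards. So was the rule for genes named in the text: DIP2, gkt and, as construct checks, w, Dcr-2 and ey; the 10 largest rises and the 10 largest falls among genes past the test that moved the same way in all 4 knockdown-control pairs, with the next 5 named genes in each direction where there were more; up to 4 passing members of each list, and otherwise its 2 members with the smallest p, given as values. Other names were chosen after their values were seen.

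The steps were tested on simulated data with the 9646 real gene means, the fitted spread and 200 changed genes, in 20 simulations. The limma step recovered 51.9% of changes of 1 on the log2 scale, 94.7% of changes of 2 and 98.3% of changes of 3, and 4.65% of its calls were false. With no effect it called 0 genes, and on average 39.7 genes were at least 1.5-fold apart in every pair. The noise was independent between genes and its spread was drawn from limma's own fitted prior, so these error rates hold for such data only. Correlation between genes, spread that depends on intensity and a deviating array were not simulated.

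The alternatives were a replicate block, leaving out each array, scaling to the median of the tested probes, quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, only probes well above background on all 4 arrays, outlier-marked spots kept, the mean of a gene's probes, the deposited value table, and an intensity trend in eBayes. All 4 arrays lay on 1 slide and in 1 scan, so a slide block was not run. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R tables used data.table (version 1.17.8).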

Results

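RNA from the central brain of pupae labelled female was measured at 24 h after puparium formation on 4 single-colour arrays, 2 of control and 2 of DIP2 knockdown. OK107-Gal4 is an enhancer trap beside ey that is widely used to drive transgenes in the mushroom body, and UAS-dicer2 strengthens RNA interference. Non-control spots were well above background for 60.9% and 64.3% of spots in control replicates 1 and 2, and for 67.7% and 68.9% in knockdown replicates 1 and 2. No spot was saturated. Across genes the control arrays correlated at 0.992, the knockdown arrays at 0.995, and arrays of different groups at 0.987 to 0.992, so control replicate 2 was as close to the knockdown arrays as to control replicate 1. The replicated probes of control replicate 1 had the highest median coefficient of variation (7.07%, against 4.04% in control replicate 2).

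The comparison asked which transcripts differ when DIP2 is knocked down, a study whose title names glaikit and axonal bifurcation in the mushroom body. DIP2 itself (CG7020, probe on 3L from 250328 to 250387) had a normalised log2 signal of 2.16 and 2.30 in the controls and 2.02 and 1.96 in the knockdown arrays. The difference was -0.24 ± 0.12 (SE, n = 2 per group), with an adjusted p = 0.718, so the targeted gene did not pass the test in whole central brain, although its signal was lower in all 4 knockdown-control pairs. The other 3 DIP2 probes gave differences of -0.26, -0.03 and -0.36. The gene gkt (CG8825), which encodes tyrosyl-DNA phosphodiesterase, had a mean of 1.86 ± 0.02 (SD, n = 2) in control and 0.95 ± 0.05 (SD, n = 2) in knockdown, a difference of -0.91 ± 0.11 (SE) or 1.88-fold. Its p was 0.000444 in limma and its adjusted p = 0.0726, which missed the threshold over all genes. Both gkt probes were lower in the knockdown arrays (2L from 3162078 to 3162137, -0.91, and from 3162270 to 3162329, -1.28). With the mean of its probes the gkt adjusted p was 0.0444, with an intensity trend 0.0109, and over all alternatives it ranged from 0.00447 to 0.723. None of the construct-check genes differed past the threshold, and both groups carried OK107-Gal4 and UAS-dicer2. The gene ey differed by -0.23 ± 0.11 (SE), Dcr-2 by -0.18 ± 0.14 and w by -0.06 ± 0.29. The second probe of ey differed by -0.09, and those of Dcr-2 (0.20) and w (0.06) went the other way.

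In DIP2 knockdown, 20 of 9646 genes passed the test, 10 higher and 10 lower, and all 20 moved the same way in all 4 pairs. The falls included genes whose signal went from well above background in control to not well above background in knockdown: TTLL15 (CG4089), a tubulin tyrosine ligase-like gene, fell at least 12.7-fold (3R from 6642997 to 6643056, adjusted p = 0.00624), CG42300 at least 16.4-fold (adjusted p = 0.0202), and mthl3, a methuselah-like receptor gene, at least 4.26-fold (adjusted p = 0.00624). P5CDh2, a pyrroline-5-carboxylate dehydrogenase gene, fell at least 6.95-fold on its brightest probe (3R from 17706252 to 17706311), which was not well above background on either knockdown array. CG31465, whose probe lies 3167 bases from it (3R from 17709478 to 17709537), fell at least 3.45-fold. Pdh, the photoreceptor dehydrogenase gene, fell from -2.86 ± 0.01 to -5.50 ± 0.11 (SD, n = 2 each, adjusted p = 0.00624). On the log2 scale, CG11052 fell by 4.02 ± 0.21 (SE) and CG3397 by 1.96 ± 0.14 (difference of its other probe -3.49), and CG3062 fell at least 2.70-fold. CG32816 fell at least 5.63-fold on its brightest probe, also not well above background in knockdown, while its other tested probe differed by 1.77 on the log2 scale in the opposite direction.

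Among genes above background in control on at least 1 array, the largest rise was that of Eig71Ej, an ecdysone-induced gene of the 71E cluster (3L from 15653706 to 15653765), from -5.90 ± 0.03 to -2.88 ± 0.15 (SD, n = 2 each, adjusted p = 0.00624), with 1 of 2 control arrays above background. GstE1, a glutathione S-transferase gene, rose by 1.79 ± 0.15 (SE) on the log2 scale and its other probe differed by 1.93. CG7900 rose by 1.25 ± 0.11 and CG1698 by 1.61 ± 0.12, the latter above background on 1 of 2 control arrays. For the other risen genes neither control array was well above background: TpnC4, a troponin C gene of muscle, rose at least 3.01-fold, CG30471 at least 3.67-fold, CheB53a at least 2.58-fold, CG31809 at least 2.58-fold, the neprilysin-like gene Nepl8 at least 2.35-fold and CG5550 at least 1.25-fold. Their adjusted p lay between 0.0269 and 0.0419 and were computed from those dim control signals.

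**Figure D1:**
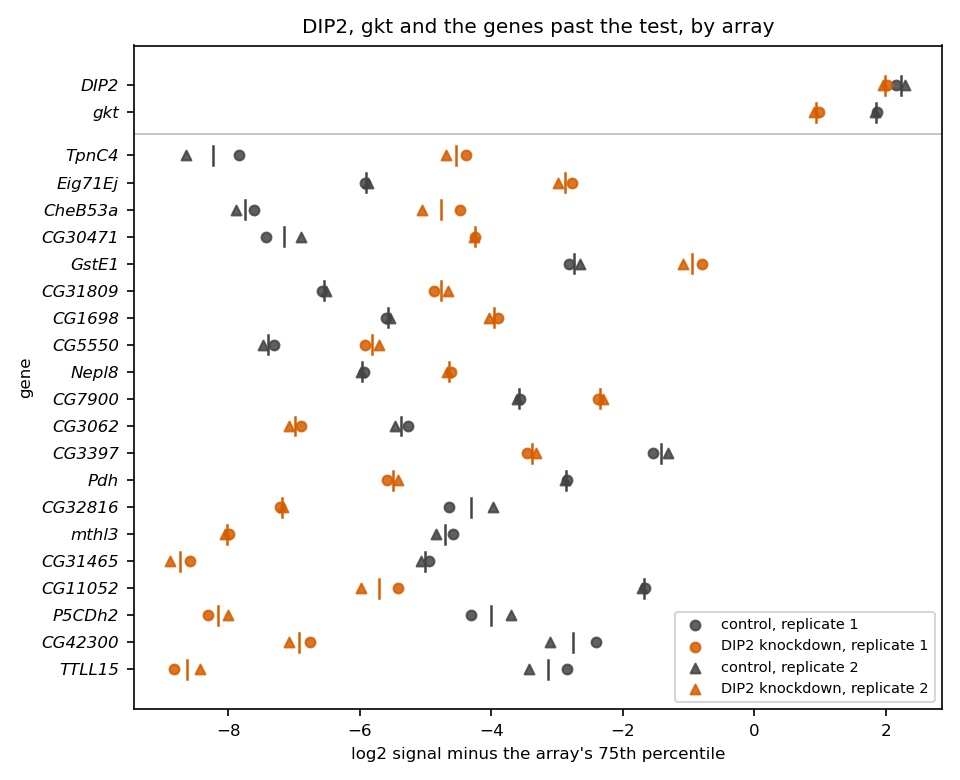
Normalised log2 signal (x axis, log2 signal minus the array's 75th percentile) of DIP2, gkt and the 20 genes that passed the test (y axis). Points are the 4 arrays, grey for control and orange for DIP2 knockdown, circles for replicate 1 and triangles for replicate 2, and short bars are group means. DIP2 differs by -0.24 and gkt by -0.91, while TTLL15 is not well above background on either knockdown array.

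The number of genes past the test depended on the settings. Median scaling gave 53 genes, 34 higher and 19 lower, and the deposited value table gave 0, with 680 genes at an unadjusted p under 0.05 against 909 here. Without knockdown replicate 1 the test passed 7 genes, and 5 of the 20 genes remained past it. Without control replicate 1, control replicate 2 and knockdown replicate 2, respectively, 10, 11 and 8 of the 20 remained.

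By size alone, 245 genes were at least 1.5-fold apart in every pair, 185 higher and 60 lower in DIP2 knockdown. In all, 36.3% of the 9646 genes had groups that did not overlap, where chance gives 33.3%. Of the 185 higher genes, 71 were not well above background on either control array, and with only probes well above background on all 4 arrays the counts were 87 higher and 45 lower. Without a filter on dim probes they were 233 higher and 240 lower, so the excess of higher genes was not kept, and the deposited value table gave 23 higher and 22 lower.

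The fat body, haemocyte, glial and cuticle lists shifted upwards at the preset correlation. Of 28 measured fat body and haemolymph genes, 25 had a positive difference and the median was 0.33 (camera adjusted p = 8.1e-05, adjusted p = 0.697 with an estimated correlation). None passed alone over all genes, with 10 higher and 1 lower at an unadjusted p under 0.05, while 2 higher genes and 1 lower gene passed adjusted over the list alone. The chitinase-like growth factor gene Idgf6 differed by 1.17 ± 0.13 (SE, adjusted p = 0.0609) and the fat body protein gene Fbp1 by 1.02 ± 0.15 (adjusted p = 0.106). Of 28 haemocyte genes, 23 had a positive difference (median 0.24, adjusted p = 0.0016, adjusted p = 0.64 with an estimated correlation); 0 passed, also adjusted over the list alone, and 9 were higher at an unadjusted p under 0.05. The scavenger receptor gene Sr-CI, with 1 of 2 control arrays above background, differed by 1.04 ± 0.24, and Hml, the hemolectin gene, was not well above background on either control array (adjusted p = 0.189). Of 28 glial genes, 24 had a positive difference (median 0.20, adjusted p = 0.00221, adjusted p = 0.697 with an estimated correlation); 0 passed on either adjustment, with 3 higher at an unadjusted p under 0.05. Their examples, the collagen gene vkg, which the haemocyte list also holds, and CG6126, differed by 0.54 ± 0.17 and 0.40 ± 0.13. Of 18 cuticle and epidermis genes, 0 passed over all genes, and 3 higher genes and 1 lower gene passed adjusted over the list alone (median 0.50, adjusted p = 0.0173, adjusted p = 0.64 with an estimated correlation). Among them Cpr97Ea, with 1 of 2 control arrays above background, differed by 0.70 ± 0.11 and the chitin deacetylase gene verm by 0.97 ± 0.19.

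Of 47 detoxification genes, 1 rose (GstE1) and 4 higher genes and 1 lower gene passed adjusted over the list alone (median 0.28, adjusted p = 0.000543, adjusted p = 0.64 with an estimated correlation). Of 38 immune and stress effector genes, 0 passed on either adjustment and 12 were higher and 2 lower at an unadjusted p under 0.05 (median 0.23, adjusted p = 0.00428, adjusted p = 0.697 with an estimated correlation). The peptidoglycan recognition gene PGRP-LB differed by 0.94 ± 0.18 and Tep2 by 0.64 ± 0.13 (its other probe 1.89).

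Neuropeptide genes and genes of energy and protein turnover shifted downwards by small amounts at the preset correlation. Without a filter on dim probes no list passed downwards (6 passed, all upwards). Of 36 neuropeptide genes, 0 passed over all genes and 1 lower gene passed adjusted over the list alone (median -0.06, adjusted p = 0.0173, adjusted p = 0.64 with an estimated correlation). That gene was Ilp2, an insulin-like peptide gene, at -1.22 ± 0.18 (SE, adjusted p = 0.106), while Ilp7, not well above background on either control array, was at least 1.34-fold higher (adjusted p = 0.392). Of 35 proteasome genes (median -0.09) and 72 oxidative phosphorylation genes (median -0.10), 0 passed on either adjustment, with 0 proteasome genes and 2 oxidative phosphorylation genes at an unadjusted p under 0.05. Those 2, ND-SGDH and ND-51L1, were higher in knockdown, against the list. Both lists had an adjusted p = 0.00555, and an adjusted p = 0.697 with an estimated correlation. Their members with the smallest p were Prosalpha1 (0.29 ± 0.14), Prosalpha3 (-0.24 ± 0.14), ND-SGDH (0.41 ± 0.14) and ND-51L1, which was not well above background on either control array; the other probe of ND-SGDH differed by -0.09.

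None of these 9 list calls held with an estimated correlation or in the directional fry test. In fry's mixed test the cuticle and neuropeptide lists passed (adjusted p = 0.0149 each). On ranks at the preset correlation all 9 passed, and so did the ecdysone list (adjusted p = 0.0315). With an estimated correlation camera has only the 2 residual degrees of freedom, so failing it cannot separate correlation between genes from few arrays. The detoxification list's estimated correlation was -0.0017, below the preset 0.01, yet its unadjusted camera p went from 4.53e-05 to 0.0388. Without control replicate 1, the array with the lowest share of spots above background, the glial (median 0.11, adjusted p = 0.12), immune (0.10, 0.607), neuropeptide (-0.05, 0.12), oxidative phosphorylation (-0.05, 0.12) and proteasome (-0.04, 0.154) lists no longer passed and the muscle list did (0.23, 0.00145). The haemocyte and detoxification lists still passed, with medians that went from 0.24 to 0.11 and from 0.28 to 0.15. Without control replicate 2 the cuticle list (0.35, 0.2) and the neuropeptide list (0.0547) no longer passed, although the neuropeptide median was larger (-0.11), and the immune median was 0.46. The cuticle list also failed without knockdown replicate 1 (0.30, 0.0669), and the oxidative phosphorylation (-0.06, 0.0798) and proteasome (-0.07, 0.0744) lists without knockdown replicate 2.

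The lists closest to the study's subject did not pass. Of 30 mushroom body neuron genes 0 passed on either adjustment and 0 had an unadjusted p under 0.05 in limma (median 0.01, list adjusted p = 0.596), with Hr51 at -0.28 ± 0.11 and the dopamine receptor gene Dop1R1 at 0.34 ± 0.14 (its other probe -0.04). Of 53 axon guidance and branching genes 0 passed on either adjustment, with 1 higher and 2 lower at an unadjusted p under 0.05 (median 0.03, list adjusted p = 0.946). The glypican gene dlp differed by 0.43 ± 0.13 (its other probe 0.09) and trn by -0.34 ± 0.12. Of 31 JNK pathway genes 0 passed on either adjustment and 2 were higher at an unadjusted p under 0.05 (list adjusted p = 0.41), Ilp8 at 1.24 ± 0.40, with 1 of 2 control arrays above background, and grnd at 0.50 ± 0.19. Of 46 synaptic transmission genes 0 passed on either adjustment and 1 was higher at an unadjusted p under 0.05 (list adjusted p = 0.41), Ace at 0.41 ± 0.15, with Ddc at -0.28 ± 0.13. In the DNA repair and topoisomerase list (38 genes, list adjusted p = 0.311), 0 passed over all genes, and 2 higher genes and 1 lower gene passed adjusted over the list alone. The lower one was gkt, and the photolyase gene phr differed by 0.93 ± 0.13 (adjusted p = 0.0942, its other probe 0.36).

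Among the remaining lists, 1 of 29 muscle genes rose (TpnC4, also adjusted over the list alone), and the list adjusted p was 0.15. Adjusted over the list alone, 1 higher gene passed in each of the ecdysone response, neuroblast and cell cycle, and small RNA pathway lists. These held 34, 43 and 28 genes, with list adjusted p = 0.102 (0.0315 on ranks), 0.243 and 0.946. The genes were ImpL1 (1 of 2 control arrays above background) at 1.48 ± 0.21, grh at 0.90 ± 0.13 and aub at 1.26 ± 0.21. Over all genes 0 members of these lists passed, with 3, 3 and 2 genes at an unadjusted p under 0.05; ImpE3 (0.49 ± 0.14), Orc2 (-0.48 ± 0.13) and vas (-0.58 ± 0.16) were their other examples. No gene passed on either adjustment in the lists of lipid and acyl-CoA metabolism (42 genes, list adjusted p = 0.41), heat shock and chaperones (24 genes, 0.342), cytosolic ribosomal proteins (84 genes, 0.449), photoreceptors and optic lobe (32 genes, 0.946) and dosage compensation and sex (17 genes, 0.894). At an unadjusted p under 0.05 these lists held 3, 1, 2, 3 and 0 genes in limma. Their examples were laza (0.64 ± 0.15) and Acox57D-d (-1.19 ± 0.29), and Hsp110 (0.58 ± 0.14, other probe -0.11) and l(2)efl (-0.55 ± 0.30). Next came RpS21 (-0.87 ± 0.12, other probe 0.22) and RpS20 (0.36 ± 0.14, other probe 0.01). The last were ninaD (0.93 ± 0.24) and ninaA (-1.23 ± 0.35), and Yp3 (1.46 ± 0.74) and roX1 (-0.87 ± 0.65). Of all these examples, ninaD was above background on 1 of 2 control arrays and Acox57D-d on 1 of 2 knockdown arrays. Median, mean and test differed in sign, with medians within 0.02 of 0, for the mushroom body, dosage compensation and photoreceptor lists. Without knockdown replicate 1 the ecdysone (0.00791), ribosomal protein (0.0473) and heat shock (just under 0.05) lists passed, and without knockdown replicate 2 the mushroom body (0.0143), neuroblast (0.0024) and synaptic (0.0024) lists did.

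**Figure D2:**
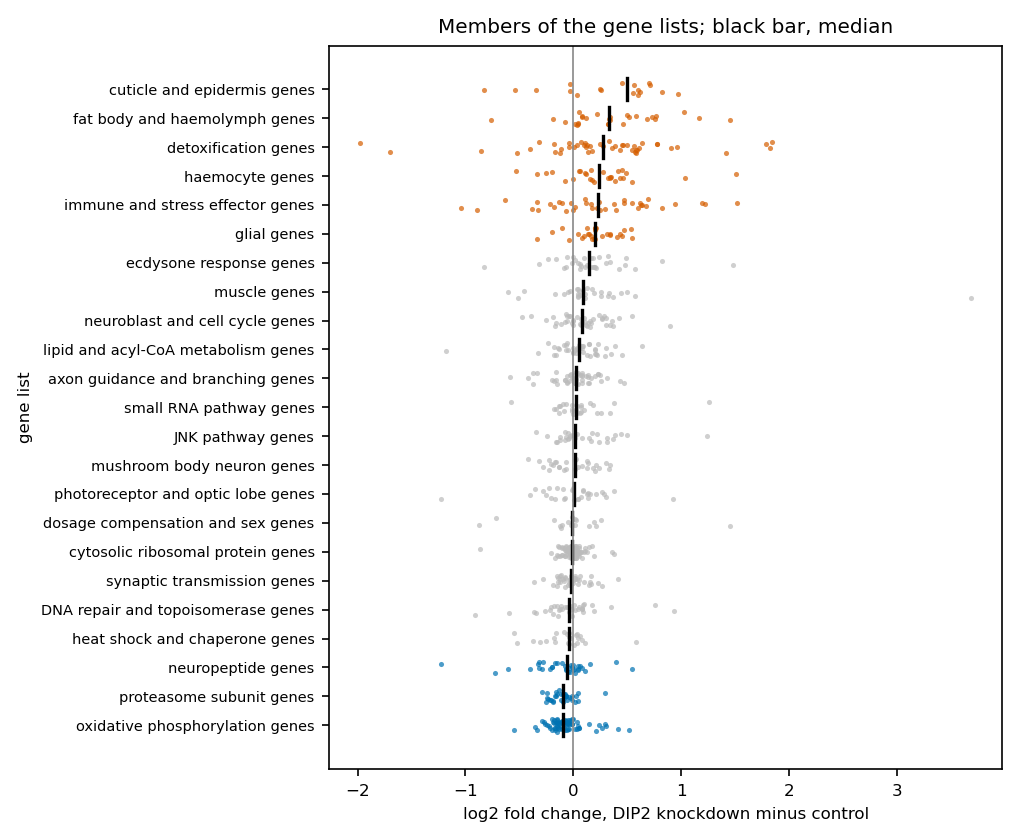
Log2 fold change of DIP2 knockdown over control (x axis) for every measured member of 23 gene lists (y axis), with 1 point per gene and a black bar at the list's median. Orange and blue mark lists that passed camera upwards and downwards, and grey marks lists that did not. The medians of the 9 lists that passed run from -0.10 for oxidative phosphorylation to 0.50 for cuticle and epidermis.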

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

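Probes that match no gene in the reference table entered no comparison above, and some differed between the groups. Of 5163 such probes well above background on both arrays of a group, 134 were at least 1.5-fold higher and 59 at least 1.5-fold lower in DIP2 knockdown in every pair. With limma over these probes alone, 10 higher and 14 lower probes had an adjusted p under 0.05.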

How the results depend on the processing

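DIP2 stayed lower and short of the threshold under every alternative (log2 difference -0.40 to -0.17), and gkt stayed lower under every alternative (-1.09 to -0.81). The gkt difference passed the test with the mean of its probes (-1.09), with an intensity trend (-0.91) and with a second normexp correction (-0.86). The number of genes past the test was 53 with median scaling and 55 with the mean of a gene's probes. It was 83 with an intensity trend and 75 at an adjusted p under 0.1. With only probes well above background on all 4 arrays it was 3, all lower, and only 5 of the 20 genes were tested there. Without a filter on dim probes it was 0 (973 genes at an unadjusted p under 0.05), where 13114 genes were tested. The deposited value table gave 0 (680 at an unadjusted p under 0.05). Leaving out 1 array gave 7 to 30 genes. Genes at least 1.5-fold apart in every pair numbered 473 without the filter, 132 with probes above background on all 4 arrays, 45 in the value table, 82 at 2-fold, and 406 to 717 with an array left out, where fewer pairs have to meet the rule. The lists past camera numbered 0 with an estimated correlation and 0 with fry's directional test, and 5 to 11 with an array left out. Camera on ranks passed 10 lists, and camera without a filter on dim probes passed 6, all upwards. The cause of the other differences was not tested.

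The planned normexp correction gave 0 genes past the test (167 at an unadjusted p under 0.05), 65 genes at least 1.5-fold apart and 14 lists. Its fitted background mean was -467 in knockdown replicate 1 and 4.62 without the 9 spots there whose local background was over 3 times the median. This distorted dim genes of that array and turned the sign of CG3062 (0.74), CG31465 (0.77), CG32816 (0.30), P5CDh2 (0.26), mthl3 (0.61), Acox57D-d (0.80), Orc2 (0.59), ninaA (0.67) and vas (0.75). The sign of w, well above background on all 4 arrays, turned as well (0.43). Camera's direction turned for the axon guidance (median -0.0712, adjusted p = 0.0428) and photoreceptor (0.52, adjusted p = 0.0194) lists, which passed camera only in that fit. The photoreceptor median was positive in the main fit too (0.0067). The axon guidance median was also negative without control replicate 1 (-0.03) or knockdown replicate 2 (-0.02). The second normexp correction, chosen after seeing the data, left out such spots. It gave 122 genes past the test, 79 higher and 43 lower, of which 13 were among the 20, and 79 genes at least 1.5-fold apart, 45 higher and 34 lower. The w difference, close to 0, also turned positive there (0.0387), with the mean of its probes (0.00346), and without control replicate 1 (0.36) or knockdown replicate 1 (0.01), and ranged from -0.47 (without control replicate 2) to 0.36 with an array left out, while Dcr-2 did with the mean of its probes (0.0092). Across all named genes and alternatives, 14 comparisons gained and 129 lost the threshold, and 808 kept their call; for lists these were 12, 19 and 327.

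With a replicate block, 21 genes passed (14 of the 20 among them), and 9 lists. Deviations of same-numbered arrays correlated at -0.03 across genes. On depth, 11 of the 20 genes were not well above background in one of the groups on any probe, which limits their folds to bounds.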

Other observations

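The tests of probes, chromosomes, splits of the arrays, lists that pass without control replicate 1, and the roX1 range and its share were chosen only after the results were seen, as were the genes named here; the adjusted p, the replicate block and leaving out arrays were planned. Among insulin-like peptide genes, none of which passed, Ilp2 had log2 signals of 1.86 and 1.85 in control and 0.86 and 0.41 in knockdown (adjusted p = 0.106), and Ilp5 of 2.13 and 2.22 against 1.92 and 1.21 (adjusted p = 0.559), and Ilp3 and Ilp1 differed by -0.01 ± 0.15 and -0.10 ± 0.19 (SE). With the second normexp correction the Ilp2 adjusted p was 0.00168, and over all alternatives it ranged from 0.00168 to 0.723. Within the detoxification list some genes went against the list: the cytochrome P450 genes Cyp6a17 and Cyp6a13 differed by -1.98 ± 0.29 and -1.70 ± 0.49 (adjusted p = 0.106 and 0.321). On 2R, mthl4 differed by 1.25 ± 0.21 (adjusted p = 0.129) while the neighbouring mthl3 fell.

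Many genes with large differences were well above background in 1 group only, and 245 genes were at least 1.5-fold apart in every pair. Of the 245, only 68 had several tested probes, and the rest could not be checked for a sequence difference under single probes. It is argued against for these 68 as a set. Their other probes reached more than 0.5 of the chosen probe's log2 difference in 75% of them, and went the same way in 61. But 14 of the 20 genes past the test had 1 tested probe and stay open as a set. For Eig71Ej, a probe without a gene match that starts within its probe (3L from 15653755 to 15653887) went the same way, by 2.93. Linkage to the hairpin insertion, which the genotype notation places on chromosome 3, stays open. The odds ratio of chromosome 3 against 2 was 0.66 (95% interval 0.479 to 0.906) for the higher genes. For the lower genes it was 1.13 (0.640 to 2.01). These ratios cannot decide it, since chromosome 2 may differ between the crosses too. Higher genes were 74 of 4210 on chromosome 3, 97 of 3675 on chromosome 2 and 9 of 1597 on X. Only 13 of 1597 X-linked genes were among the 245, an odds ratio of 0.264 (0.150 to 0.466) against chromosomes 2 and 3 over 10 bins of signal; autosomes that differ between the crosses may account for this, but gene content differs too and genotype and cross cannot be told apart. The other splits of the 4 arrays gave at most 38 genes, 1 of the 3 splits (the real one) gave as many as 245, and 3 splits are too few for a share under 0.05; an effect of the knockdown was not separated from these.

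At the preset correlation the fat body, haemocyte and glial lists lay higher and the neuropeptide, proteasome and oxidative phosphorylation lists lower in knockdown. With an estimated correlation, a test left with 2 residual degrees of freedom, none of them passed (adjusted p = 0.64 or 0.697). Members of the fat body list went apart, although 25 of 28 had a positive difference. Fbp1 differed by 1.02 (0.86 without control replicate 1), Lsp1alpha by 0.77 (0.44), Lsp1gamma by 0.73 (0.29) and Lsp1beta by 0.69 (0.42). Fbp2 differed by 0.51 (0.17) and Lsp2 by 0.34 (0.21), against -0.77 for Gbp1 (-0.78), -0.19 for Adh (-0.16) and 0.04 for Apoltp (-0.12). Control replicate 1 alone stays open: of the 9 lists, 4 passed without it (fat body, detoxification, haemocyte and cuticle, with medians at 0.691, 0.547, 0.484 and 0.799 of those with it) and 5 did not. Fat body RNA carried along in dissection and a response of these tissues to the knockdown both stay open, as neither was tested.

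The male-specific RNAs roX1 and roX2 differed between arrays of animals labelled female. Log2 signals of roX1 were 3.21 and 1.73 in control replicates 1 and 2 and 2.31 and 0.89 in knockdown replicates 1 and 2, and those of roX2 1.24, -0.56, 0.26 and -1.01. A scaling difference shared by genes of similar level is argued against, since the roX1 range of 2.32 exceeded that of 99.9% of 1156 such genes. This rank cannot decide on array quality, since roX1 was taken up after its values were seen. Differing shares of male tissue stay open. With the brighter roX2 probe, roX1 minus roX2 ranged over 0.166 of the range of roX1, where 1 source with a fixed ratio would give a small share. With the other, dimmer roX2 probe, whose own range was 1.29, it ranged over 0.441. All tested probes of both RNAs were well above background on all 4 arrays. If the shares of male tissue did differ, sex would differ between the arrays compared here. The roX1 difference between groups did not pass (-0.87 ± 0.65, adjusted p = 0.882, and 0.161 with a replicate block), although all tested probes of both RNAs were higher in replicate 1 than in replicate 2 of each group and lower in knockdown than in the control of the same number, and regulation of both RNAs in female tissue was not tested.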
